A study of Homo sapiens with 12 samples.

How the data were processed

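Gene expression was measured on 12 Affymetrix arrays of 54675 probe sets, hybridized with biotinylated cRNA made from 2 µg of total RNA of human umbilical vein endothelial cells, per the labels' protocols. RNA was extracted with silica columns. The deposited table holds 1 value per probe set and array, an intensity made by the authors with GCRMA, whose version and settings are not given in the submitters' processing notes. GCRMA corrects the background with probe sequence, quantile-normalizes the arrays and summarizes the probes of a set. Whether a further scaling followed was not stated. The deposited intensity is on the linear scale, since all values were above 0 and array medians lay between 21.2 and 22.8, and log2 was taken before any test. GCRMA draws low intensities together, so changes of weakly expressed genes depend on its background model. Each table column belonged to 1 listed array, and 0 columns were left over.

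Probe sets were joined to genes with the annotation supplied for the array. Of the 54675 probe sets, 62 controls were left out, 41097 had 1 gene symbol, 1801 had several and 11777 were not listed. Only probe sets with 1 symbol were used. A probe set was kept where at least 3 of the 12 arrays reached 4 on the log2 scale, which is 16 on the linear scale. Each gene was represented by its probe set with the highest mean over the 12 arrays, which left 13376 genes. No genome build was used, and no coordinates are given.

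The arrays fell into 4 groups of 3 biological replicates, from the labels: spread without VEGF, spread with VEGF, unspread without VEGF and unspread with VEGF. "Unspread" stands for cells on micropatterned fibronectin islands. Group membership is taken from the labels throughout, and changes are given as unspread minus spread or as VEGF minus no VEGF. Group means were fitted over all 12 arrays with limma 3.58.1 in R 4.3.3, with moderated variances and 8 residual degrees of freedom. There were 7 contrasts, the effect of each factor at each level of the other, their interaction and the average effect of each factor. P-values were adjusted by Benjamini-Hochberg over the 13376 genes within a contrast, and a gene is called changed at an adjusted p under 0.05. All tests are two-sided. Errors are standard errors of the log2 change from limma unless named as SD, and n is 3 arrays per group.

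A set of 23 gene lists and 6 lists of markers of other cell types was written from textbook knowledge. Each list was tested against the other genes with camera, at a preset correlation between genes of 0.01, and adjusted over the lists within a contrast. The same test with a correlation estimated from the data is printed beside each call that it ended. The test fry asks whether the genes of a list move one way on balance. Members are counted past the threshold over all genes and, where stated, adjusted over the list alone. The lists are described by the median log2 change of their measured members.

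Genes were named by a rule. In each contrast it took the 8 largest rises and 8 largest falls among called genes whose 3 arrays in 1 group all lay beyond the 3 of the other, with 10 and 10 and no such condition for the interaction. Chance alone gives such a separation in 10% of genes with 3 arrays against 3. It also took up to 4 called members of each list with the largest change, or the 2 members with the highest mean where none was called. The genes PTK2B, PTK2, KDR, FLT1, NRP1, ANGPT2, CCN1, CCN2 and VEGFA were added in every contrast, and a further gene is not reported here. The groups, contrasts, thresholds, lists, alternatives and this rule were fixed before the data were examined. Genes named outside the rule are said to be chosen after their values were seen.

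The labels number the replicates 1 to 3 in every group. After the group means were removed, all 18 pairs of arrays with the same number correlated across genes at r of 0.173 to 0.624, with a median of 0.483. The 36 pairs with different numbers correlated at -0.391 to 0.0472, with a median of -0.225. All 12 arrays correlated best with an array of their own number, so the numbers pair the arrays. What the number stands for was not stated. A fit with the replicate number as a block, with 6 residual degrees of freedom, is therefore given beside results whose call it changes or whose count it moves by more than 1.5 times.

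Precision is limited by the number of arrays. Recovery was tested on simulated data drawn from each gene's mean and residual spread, with a small share of the genes changed. For the adhesion effect without VEGF, 9.46% of genes with an added change of 0.5 on the log2 scale were called, 66% of those with 1 and 87.7% of those with 2. The VEGF effect in spread cells gave 19.2%, 63.9% and 93.9%, and the interaction 0%, 19.7% and 75.4%. The simulated arrays were independent, without the correlation between arrays of the same number. For the VEGF effect, fewer genes were changed in the simulation than were called in the data. The shares are thus a guide and not the power of these contrasts.

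Alternatives covered the replicate block, only the arrays compared, a trended and robust variance, array weights, no filter, a stricter filter at 6 on the log2 scale, the mean of a gene's probe sets, every probe set on its own, probe sets not ending in _s_at or _x_at, a second quantile normalization, a shift of the arrays to 1 median, and each array left out in turn. Camera with an estimated correlation and fry were the alternatives for the lists. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.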

Results

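Gene expression was measured in human umbilical vein endothelial cells (HUVECs), primary cells from the lining of the umbilical cord vein, at passage 3. The cells were plated on fibronectin, a matrix protein bound by integrins. Part of them could spread over a continuous surface, and part were held on micropatterned islands that limit spreading. After 2 h of adhesion the cells received 50 ng/ml vascular endothelial growth factor (VEGF), or none, for 18 h in medium with 5% serum. This gave 12 arrays in 4 groups of 3 biological replicates, labelled spread without VEGF, spread with VEGF, unspread without VEGF and unspread with VEGF. The design asks how cell adhesion and VEGF act on gene expression, each alone and together. The arrays were alike in overall signal, with median intensities of 21.2 to 22.8 and 53.6% to 54.8% of probe sets at 16 or above. The mean correlation of an array with the others of its group was 0.979 to 0.987.

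Endothelial genes were strongly expressed. The mean over the 12 arrays was 13.79 on the log2 scale for PECAM1, a junctional adhesion molecule, 13.80 for CDH5, the endothelial cadherin, and 13.40 for VWF, the clotting protein von Willebrand factor. In a principal component analysis of the genes tested, the leading component held 42.0% of the variance and parted the arrays labelled with VEGF from those without. The next component held 15.4% and set the arrays of replicate 2 apart from most others. Before the replicate number was removed, 5 of the 12 arrays were nearest to an array of their own group, and 11 of 12 after it.

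**Figure D1:**
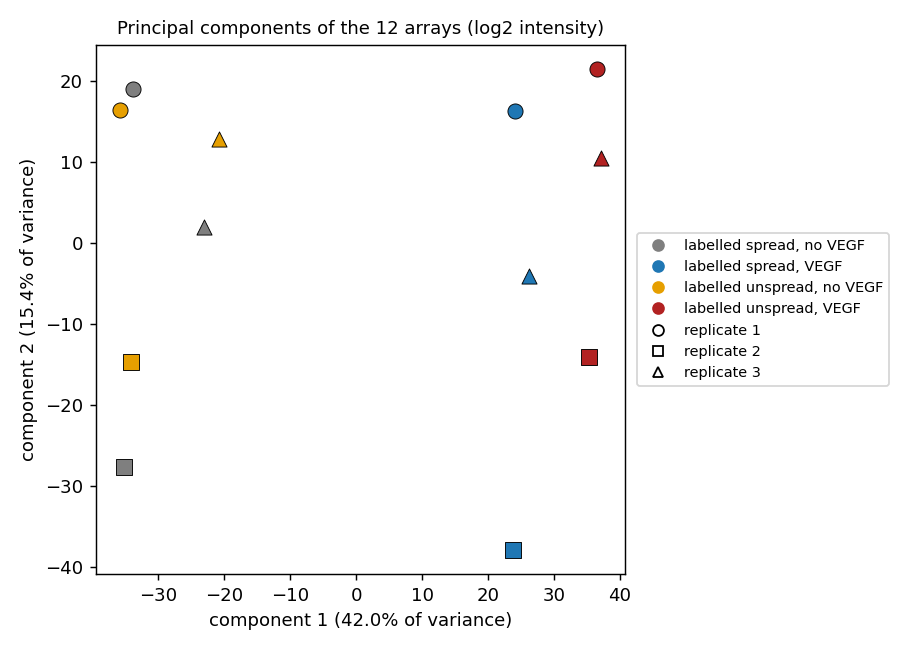
Principal component scores of the 12 arrays from log2 intensities of the genes tested, with the leading component (42.0% of the variance) on the x axis and the next (15.4%) on the y axis. Colours are the 4 groups and shapes the replicate numbers, and the arrays labelled with VEGF lie apart from those without VEGF along the x axis.

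The effect of VEGF was examined separately in arrays labelled spread and unspread. In the spread arrays, ABCA1, which exports cholesterol from cells, rose by 3.997 ± 0.195 with the VEGF label (adjusted p = 6.95e-06), and ABCG1, an exporter of the same class, by 3.33 ± 0.34 (adjusted p = 0.000443). Other large rises were CDKN1C, an inhibitor of cyclin-dependent kinases (3.38 ± 0.43, adjusted p = 0.00134), HEY1, a Notch target (2.91 ± 0.45, adjusted p = 0.00351), CH25H, which makes 25-hydroxycholesterol (2.88 ± 0.48, adjusted p = 0.00498), IL33, a nuclear cytokine (2.85 ± 0.60, adjusted p = 0.0142), and BMF, a pro-apoptotic protein (2.84 ± 0.345, adjusted p = 0.001). The falls were led by RGS4, a regulator of G protein signalling (-4.48 ± 0.60, adjusted p = 0.00162), PTX3, a secreted pattern receptor (-3.91 ± 0.31, adjusted p = 0.00015), MARCHF4, a ubiquitin ligase (-3.70 ± 0.48, adjusted p = 0.00146), CD274, the immune checkpoint ligand PD-L1 (-3.70 ± 0.31, adjusted p = 0.000195), PSAT1, an enzyme of serine synthesis (-3.69 ± 0.46, adjusted p = 0.00118), and PNMA2 (-3.48 ± 0.37, adjusted p = 0.000525). TAGLN, an actin-binding protein, fell by 3.22 (standard error 0.46, adjusted p = 0.00227), but the probe sets not ending in _s_at or _x_at gave -0.35 (adjusted p = 0.45). The lower group's mean was under the filter level of 4 for IL33 (3.09), CD274 (3.88) and PNMA2 (3.30). The sizes and standard errors of these changes thus depend on the background model. For ABCG1 the probe sets not ending in _s_at or _x_at gave 1.72, and for CD274 the mean of the probe sets gave -2.03. Without the 4 arrays of replicate 2, a setting chosen after the data were seen, the calls of CDKN1C (3.00, adjusted p = 0.0552), HEY1 (2.44, 0.0862), CH25H (2.48, 0.0648) and IL33 (3.28, 0.0718) were lost.

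In these spread arrays the genes of cholesterol and fatty acid synthesis fell together. Of 24 measured, 18 fell, 0 rose and 6 did not pass, and 21 were lower and 1 higher adjusted over the list alone. Their median was -1.52 (adjusted p = 4.19e-22, and 0.00022 with an estimated correlation). Joining the block to the estimated correlation, a setting chosen after the data were seen, gave 0.0061. DHCR7, the last enzyme of cholesterol synthesis, fell by 2.79 (adjusted p = 0.000395), MSMO1 by 2.72, SCD, the stearoyl-CoA desaturase, by 2.64, and ACAT2 by 2.48 (adjusted p = 2.68e-05). The Notch and arterial-venous list was higher, with 9 of 19 members higher, 10 adjusted over the list alone, and a median of 0.67 (adjusted p = 7.22e-06, and 0.017 with an estimated correlation, but 0.073 with the block as well). UNC5B, a netrin receptor, was among them at 1.93 (adjusted p = 0.014), and its adjusted p was 0.0529 without spread without VEGF replicate 1.

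Lists of growth and amino acid genes were lower in the same arrays. Ribosome biogenesis genes and MYC targets had 12 of 20 members lower, 13 adjusted over the list alone, and a median of -0.81 (adjusted p = 2.13e-08, but 0.073 with an estimated correlation). POLR1B, an RNA polymerase I subunit, fell by 1.43, ODC1, the first enzyme of polyamine synthesis, by 1.22, and NOLC1 by 1.02. In the ATF4 and amino acid list 12 of 27 fell, 14 adjusted over the list alone, with a median of -0.78 (adjusted p = 3.08e-08, but 0.13 with an estimated correlation). Examples were the amino acid transporter SLC7A5 (-2.73), the asparagine synthetase ASNS (-2.69) and the mitochondrial folate enzyme MTHFD2 (-2.41). Chaperones of the endoplasmic reticulum had 3 of 19 lower, 7 adjusted over the list alone, and a median of -0.31 (adjusted p = 0.000293, but 0.1 with an estimated correlation). These 3 were HSPA5, HYOU1 and PDIA6. Their calls were lost with only the 6 arrays compared (0.0887, 0.0792 and 0.128). They were also lost without single arrays, at an adjusted p of up to 0.0942, 0.0589 and 0.143, and without the 4 arrays of replicate 2. The hypoxia and glycolysis list had 3 members higher, 9 lower and 16 not past the test, 3 and 11 adjusted over the list alone, and a median of -0.33 (adjusted p = 0.00523, but 0.073 with an estimated correlation). The glucose transporter SLC2A3 rose by 2.20 and the lactate dehydrogenase LDHA fell by 1.37. Only the 6 arrays compared ended the calls of LDHA (0.0578), NOLC1 (0.0604) and POLR1B (0.0609), and the mean of its probe sets gave -1.43 for MTHFD2.

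The cytoskeletal and YAP/TAZ lists were lower with the VEGF label in the spread arrays. Of 23 targets of the YAP/TAZ coactivators, 8 fell and 1 rose, 13 and 4 adjusted over the list alone, with a median of -0.77 (adjusted p = 0.000259, but 0.073 with an estimated correlation). The scaffold AJUBA fell by 2.08 (adjusted p = 0.001) and CCN2, a matricellular protein, by 0.81 (adjusted p = 0.00796), while F3, tissue factor, rose by 2.39 (adjusted p = 0.00555). The related CCN1 was at -0.77 (adjusted p = 0.0612, 0.00953 with the replicate block, 0.0436 without spread with VEGF replicate 1 and 0.0437 without unspread with VEGF replicate 1). In the actin and MRTF/SRF list 6 of 29 fell and 1 rose, the same counts as adjusted over the list alone, with a median of -0.30 (adjusted p = 0.000461, but 0.13 with an estimated correlation). Probe sets not ending in _s_at or _x_at gave 0.05 for MYL9 (adjusted p = 0.919) and -0.35 for TAGLN (0.45), both called lower. The list was not tested with those probe sets. The calls of MYL9, VCL and MYLK, the last of them the rise, were lost without any of 6, 5 and 4 arrays. Tubulin and microtubule genes had 2 of 17 lower and 1 higher, 5 and 1 adjusted over the list alone, with a median of -0.42 (adjusted p = 0.00427, but 0.075 with an estimated correlation). TUBB2A, a beta tubulin, fell by 1.61 (adjusted p = 0.00167) and STMN1, which destabilizes microtubules, rose by 0.86 (adjusted p = 0.014).

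The endothelial, FOXO and TGF-beta lists were higher in the same arrays. The endothelial identity list had 9 of 27 higher and 0 lower, 11 and 1 adjusted over the list alone, with a median of 0.45 (adjusted p = 1.73e-05, but 0.077 with an estimated correlation). SOX7, a transcription factor of endothelial cells, rose by 1.17 (adjusted p = 0.00813). FOXO and quiescence genes had 10 of 25 higher and 1 lower, 11 and 2 adjusted over the list alone, with a median of 0.32 (adjusted p = 1.97e-05, but 0.058 with an estimated correlation). They included the insulin receptor substrate IRS2 (1.76), YPEL3 (1.67), the cyclin CCNG2 (1.39) and KLF4 (1.26). The TGF-beta and BMP list had 8 of 25 higher and 1 lower, 13 and 2 adjusted over the list alone, with a median of 0.62 (adjusted p = 9.95e-05, but 0.073 with an estimated correlation). LTBP1, which binds latent TGF-beta, rose by 1.81. The interferon list had 2 of 12 higher, also adjusted over the list alone, and a median of 0.50 (adjusted p = 0.00523, but 0.16 with an estimated correlation), with BST2, which tethers virus particles, at 1.03 (adjusted p = 0.0108). The calls of BST2 (0.052) and SOX7 (0.0531) were lost with only the 6 arrays compared.

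Cell cycle genes varied more between replicates. In the DNA replication list 1 of 28 fell (UHRF1, which maintains DNA methylation, -2.32, adjusted p = 0.0104) and 1 rose (MCM7, a helicase subunit, 1.05, adjusted p = 0.0163), the same counts as adjusted over the list alone. The list median was -0.38 (adjusted p = 0.00273, but 0.53 with an estimated correlation), and it was -0.28 with an adjusted p of 0.168 without spread without VEGF replicate 2. The MCM7 call ended without spread without VEGF replicate 1 (0.0588) or spread with VEGF replicate 3 (0.0621). Mitosis genes had a median of -0.50 (adjusted p = 0.121, and 0.024 with the replicate block, but 0.63 with an estimated correlation and the block), with 0 of 27 called. They passed without spread without VEGF replicate 1 (-0.98, adjusted p = 0.00285), spread with VEGF replicate 2 (-0.59, 0.049) or unspread without VEGF replicate 2 (-0.50, 0.0497). The list of p53 targets and cell cycle inhibitors had 3 of 19 higher and a median of 0.22 (adjusted p = 0.0642, and 0.0367 with the block, but 0.32 with an estimated correlation and the block), with BTG1, an antiproliferative factor, at 1.14 (adjusted p = 0.00268). That list passed without spread without VEGF replicate 1 (0.00966) or 3 (0.0225) or spread with VEGF replicate 2 (0.0141).

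The remaining lists did not pass camera in the spread arrays. The VEGF and ERK response list had a median of 0.26 (adjusted p = 0.0981), with 6 of 31 higher and 1 lower, 7 and 1 adjusted over the list alone. The transcription factor JUNB rose by 2.15 (adjusted p = 0.000485) and the cyclin CCND1 fell by 2.58 (adjusted p = 0.000616). RCAN1, a calcineurin inhibitor known to be induced by VEGF in endothelial cells, was at -0.90 ± 0.36 (adjusted p = 0.144, and 0.0244 with the block). The list's median was 0.23 with an adjusted p of 0.0171 without spread with VEGF replicate 2. Tip cell and angiogenic factors had a median of 0.18 (adjusted p = 0.112, and 0.0346 with the block, but 0.32 with an estimated correlation and the block), with 6 of 26 higher and 1 lower, the latter the peptide hormone APLN at -1.48 (adjusted p = 0.00796). Extracellular matrix genes had 3 of 33 higher and 1 lower (median 0.17, adjusted p = 0.0991), with the proteoglycan VCAN at 2.54 and the calcification inhibitor MGP at 2.21 among the rises and LOX, which crosslinks collagen, at -1.82. The matrix list passed without spread without VEGF replicate 1 (0.0211) or spread with VEGF replicate 3 (0.0178). Integrins and focal adhesion genes had 2 of 26 higher and 4 lower (median -0.16, adjusted p = 0.129), with ITGA2, a collagen receptor subunit, at 1.39. Matrix proteolysis had 1 of 23 higher, the inhibitor TIMP1 at 0.99 (median 0.08, adjusted p = 0.121). NF-kB genes had 1 of 21 higher, with a median of -0.13, a mean of -0.11 and a camera direction upward (adjusted p = 0.773). Apoptosis regulators had 2 of 22 higher (median 0.09, adjusted p = 0.386), BMF and the pro-apoptotic BCL2L11 at 2.71 ± 0.44 (adjusted p = 0.00438). With only the 6 arrays compared the calls of ITGA2 (0.0575) and TIMP1 (0.0642) were lost, and the mean of the probe sets gave 1.41 for BCL2L11 and 3.46 for MGP.

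For the genes of VEGF and adhesion signalling named in advance, FLT1, a VEGF receptor, was higher by 0.83 ± 0.21 in the spread arrays (adjusted p = 0.0278) and NRP1, a VEGF coreceptor, by 0.65 ± 0.18 (adjusted p = 0.0438). The FLT1 value was 0.31 (adjusted p = 0.438) with the mean of its probe sets, 0.57 (0.295) with those not ending in _s_at or _x_at and not called with only the 6 arrays compared (0.111). That call was also lost without spread without VEGF replicate 2 (0.0788) or spread with VEGF replicate 1 (0.0719) or 3 (0.1). The NRP1 call was lost whichever array was left out except unspread without VEGF replicates 1 and 3, with an adjusted p of up to 0.131 without spread without VEGF replicate 1. It was lost as well with only the 6 arrays compared (0.0992), array weights (0.0607), no filter (0.0601), the mean of the probe sets (0.0518) and the shift to 1 median (0.072). KDR, the main VEGF receptor, was at 0.55 ± 0.165 (adjusted p = 0.0574, 0.00741 with the block and 0.0344 without spread without VEGF replicate 3), and VEGFA at 0.53 ± 0.27 (adjusted p = 0.258, and 0.0187 with the block). The adhesion kinases PTK2 (0.25, adjusted p = 0.34) and PTK2B (0.04, adjusted p = 0.85) and the angiopoietin ANGPT2 (1.06 ± 0.67, adjusted p = 0.365) did not pass. In all, 1444 of 13376 genes were called, 694 higher and 750 lower, and 586 of them changed at least 2-fold. The fit with the replicate block called 2701 genes, among them all 1444. The count was 842 without spread without VEGF replicate 1, 824 without spread without VEGF replicate 2 and 759 without spread with VEGF replicate 3. Among the 80 named genes called, 51 kept the call whichever array was left out. Without the 4 arrays of replicate 2 the calls of UNC5B, ASNS, POLR1B, CCN2, F3, BST2, IRS2, KLF4, SOX7, BTG1, MCM7, ITGA2, LOX, TIMP1, FLT1 and NRP1 were lost too, with adjusted p of 0.0544 for TIMP1 to 0.27 for NRP1.

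In the arrays labelled unspread, the VEGF label went with changes of many genes. ABCG1 rose by 4.01 ± 0.34 (adjusted p = 7.77e-05) and ABCA1 by 3.79 ± 0.195 (adjusted p = 5.16e-06). STC1, a secreted glycoprotein, rose by 4.72 ± 0.69 (adjusted p = 0.00139), ARHGAP6 by 4.68 ± 0.35 (adjusted p = 3.4e-05), PMCH, a neuropeptide precursor, by 4.42 ± 0.65 (adjusted p = 0.00151), its relative PMCHL1 by 3.87 ± 0.30 (adjusted p = 4.79e-05) and CRHBP, which binds corticotropin-releasing hormone, by 3.77 ± 0.24 (adjusted p = 1.58e-05). CEMIP, which degrades hyaluronan, rose by 5.91 ± 0.59 (adjusted p = 0.000189), while its probe sets not ending in _s_at or _x_at gave 0.23 (adjusted p = 0.205). The falls were led by PTX3 (-5.95 ± 0.31, adjusted p = 5.16e-06), MARCHF4 (-5.03 ± 0.48, adjusted p = 0.000148), the keratin KRT7 (-4.82 ± 0.65, adjusted p = 0.000948), CD274 (-4.80 ± 0.31, adjusted p = 1.58e-05), RGS4 (-4.61 ± 0.60, adjusted p = 0.000778), the Wnt inhibitor DKK1 (-4.25 ± 0.25, adjusted p = 1.01e-05) and PNMA2 (-4.03 ± 0.37, adjusted p = 0.000117). The lower group's mean was under the filter level of 4 for ABCA1 (3.67), ARHGAP6 (3.10), CEMIP (3.43), CRHBP (2.70), PMCHL1 (3.65), CD274 (3.26) and PNMA2 (3.31). The sizes and standard errors of these changes thus depend on the background model. The mean of a gene's probe sets gave 3.07 for CEMIP and -2.65 for CD274.

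The sterol and growth lists were lower with the VEGF label in the unspread arrays too. Of 24 genes of cholesterol and fatty acid synthesis, 22 fell and 1 rose, 23 and 1 adjusted over the list alone, with a median of -1.66 (adjusted p = 2.85e-22, 0.00022 with an estimated correlation and 0.0058 with the block as well). MSMO1 fell by 3.22, DHCR7 by 3.08 and ACAT2 by 2.99. Ribosome biogenesis genes had 12 of 20 lower, 19 adjusted over the list alone, and a median of -0.93 (adjusted p = 3.27e-10, and 0.042 with an estimated correlation, but 0.098 with the block as well). The nucleolar proteins NOP16 (-1.57) and NOP2 (-1.27) were examples. The ATF4 and amino acid list had 13 of 27 lower, 14 adjusted over the list alone, with a median of -0.88 (adjusted p = 8.38e-09, but 0.14 with an estimated correlation). PSAT1 fell by 3.96, ASNS by 3.21 and PHGDH, another enzyme of serine synthesis, by 3.09. In the hypoxia and glycolysis list 3 of 28 rose and 5 fell, 3 and 8 adjusted over the list alone, with SLC2A3 at 1.89, NDRG1 at 1.62 and the glucose transporter SLC2A1 at -1.08. Its median was -0.18 (adjusted p = 0.0451, but 0.14 with an estimated correlation and 0.0554 with the block). Leaving out any of 5 arrays ended that call, namely spread with VEGF replicates 2 (0.0534) and 3 (0.0518), unspread without VEGF replicates 1 (0.0815) and 3 (0.0612) and unspread with VEGF replicate 2 (0.0722).

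The actin, tubulin and YAP/TAZ lists were lower in the unspread arrays with the VEGF label. Of 29 actin and MRTF/SRF genes 11 fell and 1 rose, 14 and 2 adjusted over the list alone, with a median of -0.48 (adjusted p = 5.66e-05, but 0.14 with an estimated correlation). FHL2, a cofactor at focal adhesions, fell by 1.495 (adjusted p = 0.0029) and the kinase MYLK rose by 1.73 (adjusted p = 0.00124). TAGLN fell by 3.80 (adjusted p = 0.000535), against -0.18 (adjusted p = 0.746) for its probe sets not ending in _s_at or _x_at. Tubulin genes had 7 of 17 lower and 1 higher, 9 and 2 adjusted over the list alone, with a median of -0.72 (adjusted p = 0.000107, and 0.036 with an estimated correlation, but 0.1 with the block as well). TUBB2A fell by 2.27, TUBA4A by 1.44 and TUBB4B by 1.34. YAP/TAZ targets had 9 of 23 lower and 2 higher, 11 and 2 adjusted over the list alone, with a median of -0.51 (adjusted p = 0.00827, but 0.14 with an estimated correlation). AJUBA fell by 2.15, the receptor kinase AXL by 2.05, CCN2 by 1.49 (standard error 0.148, adjusted p = 0.000183) and CCN1 by 1.37 (standard error 0.24, adjusted p = 0.00337).

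Among endothelial genes of the unspread arrays, 12 of 27 in the identity list rose and 1 fell, 14 and 1 adjusted over the list alone, with a median of 0.69 (adjusted p = 5.66e-05, but 0.14 with an estimated correlation). LYVE1, a hyaluronan receptor, rose by 2.90 (adjusted p = 0.00167), FLT1 by 1.53 ± 0.21 (adjusted p = 0.00101), and the adhesion molecule ICAM2 fell by 1.70 (adjusted p = 0.0031). The Notch and arterial-venous list had 5 of 19 higher, 8 adjusted over the list alone, and a median of 0.75 (adjusted p = 2.09e-05, and 0.024 with an estimated correlation, but 0.095 with the block as well), with HEY1 at 3.43 and the ligand EFNB2 at 2.07. FOXO and quiescence genes had 11 of 25 higher, 12 adjusted over the list alone, and a median of 0.45 (adjusted p = 4.17e-06, and 0.036 with an estimated correlation, but 0.095 with the block as well), with IRS2 at 2.43, CCNG2 at 1.90 and SESN3 at 1.53. TGF-beta and BMP genes had 6 of 25 higher and 1 lower, 9 and 1 adjusted over the list alone, with a median of 0.34 (adjusted p = 0.00366, but 0.14 with an estimated correlation). LTBP1 rose by 1.96, the receptor TGFBR1 by 1.13 (1.85 with the mean of its probe sets), and the ligand BMP4 fell by 2.84.

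Among VEGF and ERK response genes 11 of 31 were higher and 2 lower in the unspread arrays, 13 and 3 adjusted over the list alone, with a median of 0.42 (adjusted p = 0.000154, but 0.23 with an estimated correlation). RCAN2 rose by 3.30 (adjusted p = 0.0102), F3 by 2.87 (adjusted p = 0.00116) and MEF2C, a transcription factor, by 2.13 (adjusted p = 0.0024). RCAN1 was at 1.02 ± 0.36 (adjusted p = 0.085, and 0.0121 with the block). Tip cell and angiogenic factors had 8 of 26 higher and 2 lower, 8 and 3 adjusted over the list alone, with a median of 0.30 (adjusted p = 0.0142, but 0.14 with an estimated correlation). UNC5B rose by 1.97, while APLN fell by 3.46 (adjusted p = 4.79e-05). Matrix proteolysis had 6 of 23 higher, 8 higher and 1 lower adjusted over the list alone, and a median of 0.26 (adjusted p = 0.00428, but 0.22 with an estimated correlation). The membrane proteinases MMP14 (1.23, adjusted p = 0.00505) and ADAM17 (1.06, adjusted p = 0.00633) were among them. Interferon genes had 2 of 12 higher and a median of 0.14 (adjusted p = 0.0495, but 0.32 with an estimated correlation), with IFIT3 at 1.98. Leaving out any of 8 arrays ended that call, at an adjusted p of up to 0.217 without unspread with VEGF replicate 2.

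DNA replication genes had 6 of 28 lower and 1 higher in the unspread arrays, 7 and 1 adjusted over the list alone, with a median of -0.53 (adjusted p = 0.000234, but 0.44 with an estimated correlation). Among their falls, UHRF1 was at -1.75 (adjusted p = 0.0273). Calls of UHRF1, CDC6, PCNA and MCM2 were lost without any of 3, 9, 8 and 6 arrays (adjusted p of up to 0.137). The mitosis list was lower, with a median of -0.70 (adjusted p = 0.0223, but 0.65 with an estimated correlation) and 0 of 27 members called. Its median was 0.02 (adjusted p = 0.944) without unspread without VEGF replicate 2 and -0.27 (adjusted p = 0.371) without unspread with VEGF replicate 1. The list of p53 targets and cell cycle inhibitors was higher, with 3 of 19 members called and a median of 0.17 (adjusted p = 0.042, but 0.56 with an estimated correlation). It was -0.13 (adjusted p = 0.342) and 0.03 (adjusted p = 0.158) without the same arrays in turn. CDKN1C rose by 3.53 ± 0.43 (adjusted p = 0.000565), and by 2.24 with the mean of its probe sets. The UHRF1 call was also lost with only the 6 arrays compared (0.0606) and without a filter (0.0542).

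The lists that did not pass in the unspread arrays were integrins and focal adhesion (median -0.19, adjusted p = 0.365), extracellular matrix (0.32, 0.148), NF-kB genes (-0.09, 0.508), chaperones of the endoplasmic reticulum (0.04, 0.489) and apoptosis regulators (0.05, 0.386). Single members changed, with 3 integrin and adhesion genes higher and 4 lower, 4 and 4 in the matrix, 1 and 3 among NF-kB genes, 0 and 0 among chaperones and 3 and 0 among apoptosis regulators. ITGA2 rose by 1.93 and vinculin, VCL, fell by 1.20. LOX fell by 3.31 (adjusted p = 0.000307) and VCAN rose by 2.21. BCL2L11 rose by 3.45 (adjusted p = 7e-04, and 1.69 with the mean of its probe sets) and BMF by 3.26 (adjusted p = 0.000254). The matrix list passed without unspread without VEGF replicate 1 (0.0256) or unspread with VEGF replicate 3 (0.0413).

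Of the signalling genes named in advance, KDR rose by 0.81 ± 0.165 (adjusted p = 0.00823) and NRP1 by 1.06 ± 0.18 (adjusted p = 0.0033) in the unspread arrays. PTK2 (0.39, adjusted p = 0.116), PTK2B (-0.00, adjusted p = 0.986), ANGPT2 (-0.69 ± 0.67, adjusted p = 0.581) and VEGFA (0.04, adjusted p = 0.958) did not pass. A total of 1843 genes were called, 976 higher and 867 lower, and 866 changed at least 2-fold. A total of 3140 were called with the replicate block, among them all 1843. The count was 1210 without unspread without VEGF replicate 1, 1076 without unspread without VEGF replicate 2 and 1152 without unspread with VEGF replicate 1. Of 93 named genes called, 74 kept the call whichever array was left out. Without the 4 arrays of replicate 2 the calls of CCN1, TUBB4B, ADAM17, RCAN2, UNC5B and NRP1 were lost, with adjusted p of 0.0509 for UNC5B to 0.112 for RCAN2.

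The VEGF effects in spread and unspread arrays share no array, but the same fit gave both, with the same variance estimate per gene. Arrays of the same replicate number also correlate across the groups, so the counts for independent calls are a reference and not a test. Genes called higher in both numbered 443, against 50.6 for independent calls, and 450 were lower in both, against 48.6. No gene, 0 in all, was called in opposite directions. Across genes, which are not independent replicates, the log2 changes correlated at Pearson's r = 0.765, with a Spearman rank correlation of 0.648.

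Some lists of markers of other cell types passed camera with the VEGF label in the unspread arrays, with few of their members called. The fibroblast list (10 of 10 measured) was higher, with a median of 1.06 and 1 member called (adjusted p = 0.0274, but 0.13 with an estimated correlation). Of its genes, COL1A1, COL1A2 and POSTN are also in the matrix list, and COL3A1, a collagen, had a mean of 11.80 over all arrays. The epithelial and trophoblast list (5 of 10 measured) was lower, with a median of -1.20 (adjusted p = 0.0274, but 0.13 with an estimated correlation). Its 2 called members were KRT7 and KRT18, another keratin, at -1.97, while EPCAM, CDH1, KRT5 and CGA did not pass the filter. In the spread arrays the same lists had medians of 0.47 (adjusted p = 0.147) and -0.02 (adjusted p = 0.616). Smooth muscle and pericyte markers (7 of 10) had medians of 0.11 (adjusted p = 0.788, with a mean of -0.34 and a downward test) and -0.05 (adjusted p = 0.478) in spread and unspread arrays. Leukocyte markers (3 of 12; adjusted p = 0.931 and 0.985), erythroid markers (1 of 8; adjusted p = 0.788 and 0.478) and lymphatic markers (7 of 7; medians 0.20 and 0.24, adjusted p = 0.147 and 0.213) did not pass.

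**Figure D2:**
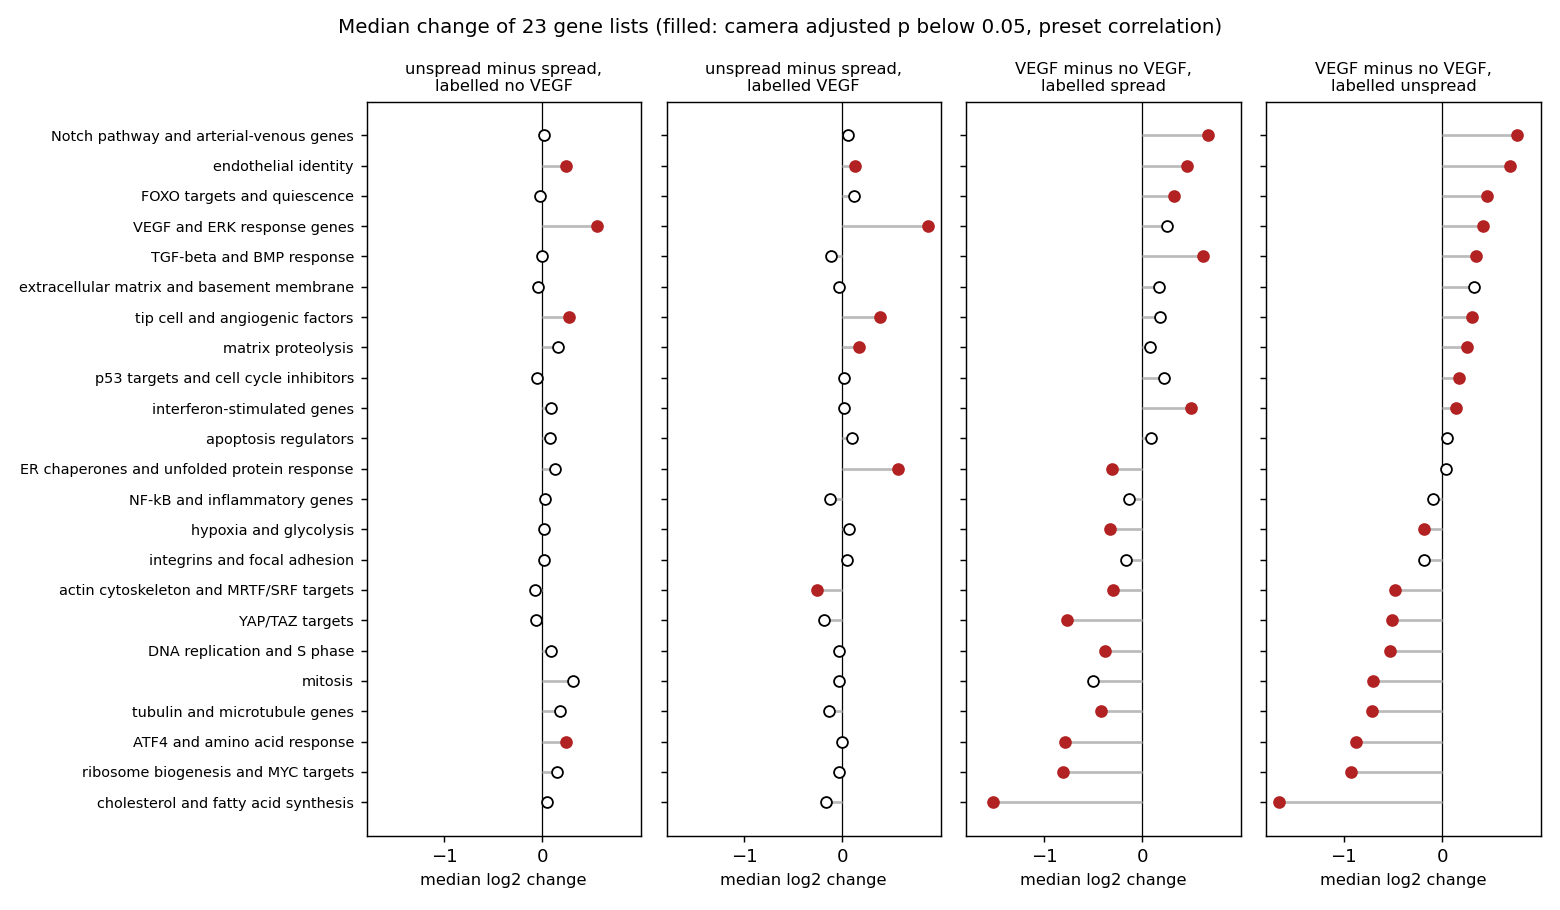
Median log2 change of the measured members of each of the 23 gene lists (x axis) for 4 comparisons, unspread minus spread without and with VEGF and VEGF minus no VEGF in spread and unspread arrays. Filled red points passed camera with its preset correlation at an adjusted p under 0.05, and the sterol list lies lowest in both VEGF comparisons, at -1.52 and -1.66.

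The effect of adhesion was examined separately with and without VEGF. In arrays labelled with VEGF, ARHGAP6 was higher in the unspread group by 4.49 ± 0.35 (adjusted p = 0.000404) and REEP1, which shapes the endoplasmic reticulum, by 3.96 ± 0.31 (adjusted p = 0.000404). STC1 rose by 4.52 ± 0.69 (adjusted p = 0.00938), STATH, a salivary peptide gene, by 4.47 ± 0.565 (adjusted p = 0.00304) and EHD3, an endocytic recycling protein, by 3.86 ± 0.39 (adjusted p = 0.00128). CEMIP rose by 4.67 ± 0.59 (adjusted p = 0.00304), while its probe sets not ending in _s_at or _x_at gave 0.20 (adjusted p = 0.497). The falls were led by DKK1 (-2.69 ± 0.25, adjusted p = 0.000778), PTX3 (-2.53 ± 0.31, adjusted p = 0.00286), the growth factor receptor EGFR (-2.04 ± 0.315, adjusted p = 0.0099, but -0.62 and 0.159 with the mean of its probe sets), MGARP (-1.88 ± 0.30, adjusted p = 0.011) and OLFML2A (-1.87 ± 0.27, adjusted p = 0.00661). CD200, an inhibitory ligand of immune cells (4.26), PMCH (3.82), ADGRG6 (-2.72), LOX (-2.02) and BMP4 (-1.94) were called too, but not without unspread with VEGF replicate 1 (adjusted p = 0.119, 0.066, 0.105, 0.0933 and 0.068). The same calls were lost without 2 or 3 further arrays labelled with VEGF, at an adjusted p of up to 0.104 for CD200 without spread with VEGF replicate 3. The lower group's mean was under the filter level of 4 for ARHGAP6 (3.29), REEP1 (3.18), STATH (3.76) and OLFML2A (3.10). The sizes and standard errors of these changes thus depend on the background model. Only the 6 arrays compared ended the calls of STC1 (0.0847), CEMIP (0.0608), EGFR (0.0655) and OLFML2A (0.102), and of CD200 (0.15), ADGRG6 (0.148), LOX (0.0655) and BMP4 (0.0648).

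The VEGF and ERK response list was higher with the unspread label in these arrays. Of 31 measured, 11 rose, 0 fell and 20 did not pass, and 14 were higher and 1 lower adjusted over the list alone, with a median of 0.87 (adjusted p = 5.14e-13, but 0.11 with an estimated correlation). RCAN1 rose by 3.02 ± 0.36 (adjusted p = 0.00235) and MEF2C by 2.84 ± 0.34 (adjusted p = 0.00274). The list's median was 0.31 higher in the arrays labelled unspread without VEGF than in those labelled spread with VEGF (adjusted p = 0.114), and higher in 2 of the 3 replicate numbers. In the list of chaperones and folding genes of the endoplasmic reticulum 2 of 19 were higher and 17 did not pass, 9 were higher adjusted over the list alone, and the median was 0.565 (adjusted p = 7.56e-09, but 0.058 with an estimated correlation). HYOU1, a chaperone of that compartment, rose by 1.07 (adjusted p = 0.00274). Tip cell and angiogenic factors had 3 of 26 higher, 7 adjusted over the list alone, with a median of 0.38 (adjusted p = 1.69e-05, but 0.058 with an estimated correlation). The growth factor HBEGF rose by 2.24 (adjusted p = 0.00235). Matrix proteolysis had 2 of 23 higher, 4 adjusted over the list alone, with a median of 0.17 (adjusted p = 0.00197, but 0.32 with an estimated correlation), led by the proteinase ADAMTS1 at 3.21 (adjusted p = 0.00173). Only the 6 arrays compared ended the calls of RCAN1 (0.0514), HYOU1 (0.0508) and HBEGF (0.0648), and the mean of its probe sets gave 1.435 for HBEGF.

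The endothelial identity list had 4 of 27 higher, 5 adjusted over the list alone, with a median of 0.12 (adjusted p = 0.0325, but 0.52 with an estimated correlation). That call was lost without spread with VEGF replicates 2 (0.0986) and 3 (0.054) and unspread with VEGF replicates 1 (0.0638) and 3 (0.0704). FLT1 was higher by 1.25 ± 0.21 (adjusted p = 0.0138, 0.0549 without spread with VEGF replicate 2 and 0.0715 without unspread with VEGF replicate 1). The actin and MRTF/SRF list was lower, with a median of -0.25, 0 of 29 members called and 5 lower and 1 higher adjusted over the list alone (adjusted p = 0.000626, but 0.32 with an estimated correlation and 0.195 without spread with VEGF replicate 2). TPM1, a tropomyosin, was at -0.64 ± 0.14 (adjusted p = 0.0533, 0.037 with the block and 0.0476 without spread without VEGF replicate 1). YAP/TAZ targets did not pass as a list, with a median of -0.19, a mean of 0.04 and an adjusted p of 0.861, although 3 of 23 members were called higher and 0 lower, 4 and 2 adjusted over the list alone. These were F3 (2.01), NT5E, an ectonucleotidase (1.53), and LATS2, a kinase that inhibits YAP (0.86), whose calls were lost without any of 9, 5 and 9 arrays. Their highest adjusted p were 0.152 for F3 without unspread with VEGF replicate 1, 0.0964 for NT5E without spread with VEGF replicate 3 and 0.135 for LATS2 without unspread with VEGF replicate 2. CCN2 was at -0.61 ± 0.148 (adjusted p = 0.0792, 0.0466 with the block and 0.0476 without unspread without VEGF replicate 1). The other 16 lists had adjusted p between 0.12 and 0.861, and of these the sterol (-0.19, 0.0284), matrix (-0.14, 0.00782) and NF-kB (-0.36, 0.0238) lists passed as lower without unspread with VEGF replicate 1. Median, mean and test did not share a sign for the mitosis, p53, YAP/TAZ, Notch, interferon and ATF4 lists. In the matrix list TGFBI, a matrix protein, fell by 1.28 (adjusted p = 0.00898). In the hypoxia list NDRG1, a stress response gene, rose by 1.12 (adjusted p = 0.00463). PTK2B (-0.03, adjusted p = 0.944), PTK2 (0.24, adjusted p = 0.58), KDR (0.29, adjusted p = 0.535), NRP1 (0.36, adjusted p = 0.478), ANGPT2 (1.12, adjusted p = 0.554), CCN1 (-0.66, adjusted p = 0.27) and VEGFA (-0.48, adjusted p = 0.536) did not pass.

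The markers of epithelial and trophoblast cells were lower in the unspread arrays with VEGF, with a median of -0.81 and 0 of 5 members called, 2 lower adjusted over the list alone (adjusted p = 0.00276, and 0.044 with an estimated correlation, but 0.075 with the block as well). The other 5 marker lists had adjusted p of 0.344 to 0.588. In all, 206 genes were called, 166 higher and 40 lower, and 137 changed at least 2-fold. The block fit called 602 genes, among them all 206. The count was 123 without spread with VEGF replicate 2, 109 without spread with VEGF replicate 3, and 95, 115 and 133 without unspread with VEGF replicates 1, 2 and 3. Of 33 named genes called, 18 kept the call whichever array was left out. Without the 4 arrays of replicate 2 the calls of RCAN1 (2.82, adjusted p = 0.139), MEF2C, HYOU1, FLT1, NDRG1, TGFBI, CEMIP, STATH, EHD3, CD200, PTX3, MGARP, OLFML2A, ADGRG6, LOX and BMP4 were lost, with adjusted p of 0.0607 for MEF2C to 0.326 for CD200. The calls of F3 (0.37), NT5E (0.344) and LATS2 (0.331) were lost there too.

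**Figure D3:**
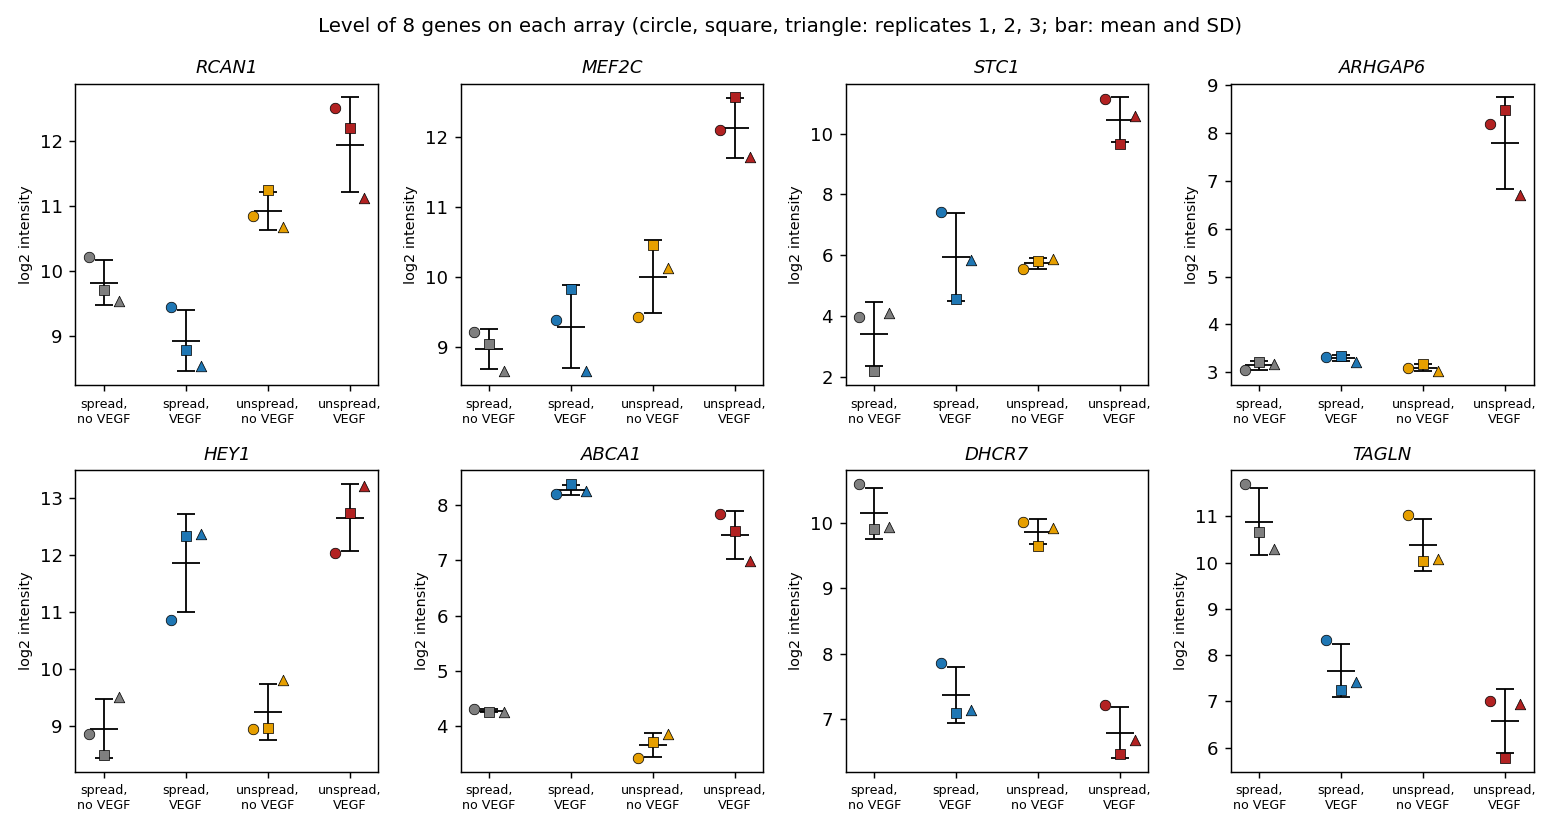
Log2 intensity (y axis) of 8 genes in each of the 12 arrays by group (x axis), with circles, squares and triangles for replicates 1, 2 and 3 and bars for the mean and SD of 3 arrays. The genes were chosen after their values were seen, and RCAN1 is higher in unspread than spread arrays while ABCA1 and DHCR7 part by the VEGF label.

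Without VEGF, the VEGF and ERK response list was higher in the unspread arrays, although no single gene passed. Their median was 0.56, with 0 of 31 called but 10 higher adjusted over the list alone (adjusted p = 1.23e-08, but 0.39 with an estimated correlation). Tip cell and angiogenic factors had a median of 0.27, with 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.000391, but 0.2 with an estimated correlation). The endothelial identity list had a median of 0.24, with 1 higher adjusted over the list alone (adjusted p = 0.00982, but 0.8 with an estimated correlation and 0.208 without spread without VEGF replicate 1). The ATF4 and amino acid list had a median of 0.24 (adjusted p = 0.024, but 0.88 with an estimated correlation). Its call was lost without spread without VEGF replicates 2 (0.268) and 3 (0.291) and unspread without VEGF replicate 1 (0.36). With the replicate block the actin list (-0.07, adjusted p = 0.0659, and 0.0442 with the block) and matrix proteolysis (0.16, adjusted p = 0.164, and 0.0442 with the block) passed too, but not with an estimated correlation and the block (adjusted p = 0.84 and 0.78). The actin list also passed without spread without VEGF replicate 1 (0.00338), spread with VEGF replicate 2 (0.038) or unspread without VEGF replicate 1 (0.00892), and matrix proteolysis without unspread without VEGF replicate 2 (0.0105). The other 17 lists had adjusted p of 0.329 to 0.887, and the 6 marker lists 0.893. Of these the matrix list passed without unspread without VEGF replicate 1 (-0.12, 0.0155) and the p53 list without spread without VEGF replicate 2 (-0.17, 0.0484). The YAP/TAZ, Notch, sterol and FOXO lists and the epithelial and trophoblast markers had a median, mean and test of unlike sign.

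The mitosis list had a median of 0.31 without VEGF (adjusted p = 0.437), but it was -0.47 (adjusted p = 0.00109) without unspread without VEGF replicate 2. It was 0.92 (adjusted p = 4.1e-05) without spread without VEGF replicate 2, 0.95 (adjusted p = 0.000467) without unspread without VEGF replicate 1 and 0.55 (adjusted p = 0.0429) without unspread without VEGF replicate 3. The DNA replication list likewise moved from 0.09 (adjusted p = 0.621) to -0.20 (adjusted p = 0.00109) without unspread without VEGF replicate 2. It was 0.24 (adjusted p = 0.00369) without spread without VEGF replicate 2 and 0.38 (adjusted p = 0.00252) without unspread without VEGF replicate 1.

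Among single genes without VEGF, ANGPT2, a tip cell ligand of the receptor TIE2, was at 2.87 ± 0.67 (adjusted p = 0.479), FLT1 at 0.56 ± 0.21 (adjusted p = 0.634) and the ligand EFNB2 at -1.05 ± 0.26 (adjusted p = 0.559), each in the same direction in all 3 replicate numbers. RCAN1 was at 1.11 ± 0.36 (adjusted p = 0.599). PTK2B (0.02, adjusted p = 0.996), PTK2 (0.10, adjusted p = 0.938), KDR (0.03, adjusted p = 0.996), NRP1 (-0.05, adjusted p = 0.988), CCN1 (-0.06, adjusted p = 0.988), CCN2 (0.07, adjusted p = 0.969) and VEGFA (0.01) did not pass either. With limma 0 of 13376 genes were called, against 959 at an unadjusted p under 0.05, and the smallest adjusted p was 0.114. With the replicate block 2 genes were called, chosen here after their values were seen, APLN at 1.98 (3.93-fold, adjusted p = 0.0205) and SMAGP at 1.06 (2.08-fold, adjusted p = 0.0205). The count was 2 without spread without VEGF replicate 3 and 1 without unspread without VEGF replicate 1, unspread without VEGF replicate 3 or unspread with VEGF replicate 1. Of the 206 genes called with VEGF, 92.7% had the same sign without it, against 56.4% of all genes, and across all genes the adhesion effects correlated at r = 0.342.

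The interaction asks whether the VEGF effect differed between unspread and spread arrays. ARHGAP6 was the 1 gene called, with a difference of 4.54 ± 0.49 (adjusted p = 0.0254, and 0.0249 with the block) and the same direction in all 3 replicate numbers. Its mean was 7.78 in the unspread arrays with VEGF and 3.10 to 3.29 in the other groups, below the filter level of 4. The call was lost without any of 10 arrays, at an adjusted p of up to 0.159 without spread without VEGF replicate 2, and was kept without unspread with VEGF replicate 2 or 3. It was also lost without a filter on low values (0.129) and without the 4 arrays of replicate 2 (4.23, 0.911). A total of 900 genes had an unadjusted p under 0.05. With the replicate block 17 genes were called, 12 higher and 5 lower, among them REEP1 (3.33, adjusted p = 0.0433), the growth factor receptor PDGFRA (2.16, adjusted p = 0.0433) and DKK1 (-2.32, adjusted p = 0.0433), chosen after their values were seen. The count of called genes was 0 without any single array of the spread groups or of the unspread group without VEGF, 2 without unspread with VEGF replicate 2 and 5 without replicate 3 of that group.

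Chaperones of the endoplasmic reticulum had an interaction median of 0.515, with 0 of 19 called and 2 higher adjusted over the list alone (adjusted p = 4.56e-06, but 0.28 with an estimated correlation). VEGF and ERK response genes had a median of 0.22, with 0 of 31 called and 3 higher adjusted over the list alone (adjusted p = 0.00677, but 0.9 with an estimated correlation). That call was lost without spread without VEGF replicate 3 (0.0883), spread with VEGF replicate 2 (0.222) or unspread with VEGF replicate 1 (0.0758). The other 21 lists had adjusted p of 0.104 to 0.942. Mitosis genes passed as lower without spread without VEGF replicate 2 (-0.97, 0.004), unspread without VEGF replicate 1 (-0.89, 0.00858) or unspread with VEGF replicate 2 (-0.75, 0.0279), and DNA replication genes without the former pair (-0.32, 0.0126 and -0.38, 0.00858). Without single arrays the actin (0.0232, spread with VEGF replicate 1), ATF4 (0.0042, spread without VEGF replicate 1), tubulin (0.0413, unspread without VEGF replicate 3) and matrix proteolysis lists (0.0476, spread without VEGF replicate 1, and 0.0413, unspread with VEGF replicate 2) passed. Signs of median, mean and test were unlike for the p53, YAP/TAZ, matrix, endothelial and apoptosis lists and for leukocyte markers. The epithelial and trophoblast markers had a median of -1.18 (adjusted p = 0.00804, but 0.068 with an estimated correlation) and the other marker lists adjusted p of 0.557 to 0.952. The signalling genes named in advance had adjusted p of 0.658 to 0.971, from CCN2 (-0.68) to PTK2B (-0.04).

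Averaged over both levels of spreading, 3215 genes were called for VEGF, 1649 higher and 1566 lower, and 786 changed at least 2-fold. The largest rise was ABCA1 (3.89 ± 0.14, adjusted p = 2.31e-07) and the largest fall PTX3 (-4.93 ± 0.22, adjusted p = 7.2e-07). FLT1 rose by 1.18, NRP1 by 0.85 and KDR by 0.68, while CCN2 fell by 1.15 and CCN1 by 1.07. PTK2 was at 0.32 (adjusted p = 0.0502, and 0.0345 with the block) and VEGFA at 0.29 (adjusted p = 0.33, and 0.0369 with the block). TMTC2, an endoplasmic reticulum protein, rose by 2.90 (adjusted p = 0.000236). Of the 23 lists, 18 passed, 9 higher and 9 lower, 5 passed with an estimated correlation, and 1 with the block as well. ABCA1 had a mean of 3.67 in unspread arrays without VEGF, under the filter level of 4.

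Averaged over both levels of VEGF, the unspread label went with changes of the following genes. For this average and the average VEGF effect, calls of single genes were followed with the replicate block and not under the other alternatives. DUSP5, an ERK phosphatase, rose by 2.26 ± 0.34 (adjusted p = 0.00843), SPRY4, an inhibitor of ERK signalling, by 2.14 ± 0.23 (adjusted p = 0.00288) and RCAN1 by 2.06 ± 0.25 (adjusted p = 0.00336). STATH (3.32), EHD3 (2.99), REEP1 (2.29), ADAMTS1 (2.17) and TM4SF18 (1.89) completed the 8 largest rises, and the group means under the filter level of 4 were all but 1 for REEP1 (3.18 to 3.95) and both spread ones for STATH (3.66 and 3.76). ADGRG6, an adhesion receptor, fell by 1.96 (adjusted p = 0.024), PLXNA4, a semaphorin receptor, by 1.02 (adjusted p = 0.00308) and the transcription factor GATA3 by 0.57 (adjusted p = 0.0196). FLT1 rose by 0.90 ± 0.147 (adjusted p = 0.0127), and ANGPT2 was at 2.00 ± 0.47 (adjusted p = 0.0677, and 0.02 with the block). Of the VEGF and ERK response genes 10 of 31 were higher, 19 higher and 1 lower adjusted over the list alone, with a median of 0.66 (adjusted p = 7.17e-15, but 0.11 with an estimated correlation), and tip cell factors a median of 0.34 (adjusted p = 5.74e-07, and 0.044 with an estimated correlation, but 0.22 with the block as well). Unlike signs of median, mean and test were found for the DNA replication, YAP/TAZ, Notch and tubulin lists.

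For this average adhesion effect 213 genes were called, 170 higher and 43 lower, and 88 changed at least 2-fold. The replicate block gave 621 genes, among them all 213. Without the 4 arrays of replicate 2, a setting chosen after the data were seen, only 2 genes were called, so nearly all calls were lost. Higher genes made up 79.8% of the calls, 71.2% after a second quantile normalization and 68.3% with the arrays shifted to 1 median. The count was 119 without spread without VEGF replicate 2, 139 and 132 without spread with VEGF replicates 2 and 3, 123 and 135 without unspread without VEGF replicates 2 and 3, and 117 and 139 without unspread with VEGF replicates 1 and 2.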

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

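The tests of exchanged group names and of a single exchanged or failed array were chosen after the result was seen. So were all 32 splits that part every pair, and leaving out all arrays of replicate 2. The other tests in this part were not.

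A gene and a pair of gene lists had a VEGF effect that differed between unspread and spread arrays by the test of the interaction itself. ARHGAP6 had a difference of 4.539 (adjusted p = 0.0254), but its mean was 3.10 to 3.29 in 3 of the 4 groups, under the filter level of 4, so the size depends on the background model. That call was lost without any of 10 arrays (adjusted p of up to 0.159, without spread without VEGF replicate 2), without a filter on low values (0.129) and without the 4 arrays of replicate 2 (0.911). VEGF and ERK response genes had a median difference of 0.224 (adjusted p = 0.00677, but 0.9 with an estimated correlation). This list call was lost without spread without VEGF replicate 3 (0.256, adjusted p = 0.0883), spread with VEGF replicate 2 (0.118, 0.222) or unspread with VEGF replicate 1 (0.105, 0.0758). Chaperones of the endoplasmic reticulum had a median difference of 0.515 (adjusted p = 4.56e-06, but 0.28 with an estimated correlation). For the count of genes called in the interaction, 9 of 100 splits of the 12 arrays gave at least the 1 gene of the real split, and the highest of the others gave 213. That split exchanges the spreading names at 1 level of VEGF, which turns the interaction into the average adhesion effect, so the splits hold a real effect and do not speak for or against chance. Of the 32 splits that part every pair of arrays with the same number, 8 gave at least 1 gene. An exchange of names between the groups labelled spread with VEGF and unspread without VEGF leaves the interaction as it is, by design, but would make every VEGF effect printed an adhesion effect and the reverse, the 3215 genes of the average VEGF effect and the 213 of average adhesion among them.

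The VEGF and ERK response list was higher with the unspread label, with and without VEGF (adjusted p = 0.11 and 0.39 with an estimated correlation), while the YAP/TAZ (0.073 and 0.14) and actin lists (0.13 and 0.14) were lower with the VEGF label in spread and unspread arrays, so all these calls are lost at that setting. Normalization was tested on the difference between the arrays labelled unspread without VEGF and those labelled spread with VEGF. For the response and actin lists at least 73% of that median difference was left under either of the other normalizations. This argues against scale differences left between arrays as its whole cause. The changes by label and the YAP/TAZ list were not in this test, and the normalization within GCRMA was not tested. A single exchanged or failed array is argued against as the whole cause, since 72 of 72 values of these 6 list calls at the preset correlation kept their sign and side of the threshold, with each of the 12 arrays left out in turn. An exchange of names between the groups labelled spread with VEGF and unspread without VEGF stays open. The response list was 0.308 higher in the arrays labelled unspread without VEGF, but its adjusted p was 0.114 and replicate 1 went the other way (-0.125). YAP/TAZ (0.657, adjusted p = 0.00207, but 0.11 with an estimated correlation) and actin genes (0.245, 0.0284, but 0.41) were higher there in all 3 numbers. For actin the difference in replicate 2 was only 0.00601. These differences are made of the same changes that raised the question, and correct names with real effects can give them too. Apart from the response list in replicate 1, their direction is the one an exchange would give. They do not decide between an exchange and correct names. A biological effect of adhesion on VEGF signalling, which the design names, stays open too and was not tested apart from the causes above.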

How the results depend on the processing

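Leaving out the 4 arrays of replicate 2, and joining the replicate block to the estimated correlation or to fry, were chosen after the data had been seen. Under every alternative that gave a value, direction and side of the threshold were kept by 30 of 80 named genes called for VEGF in spread arrays, 61 of 93 for VEGF in unspread arrays, 4 of 33 for adhesion with VEGF and 0 of 1 for the interaction. Among called lists 1 of 14, 1 of 18, 0 of 6 and 0 of 2 did so, and 0 of 4 for adhesion without VEGF. Counted as values, each a call under 1 alternative, they were kept in 1581 of 1815, 1958 of 2104, 616 of 746 and 9 of 21 for genes, and in 279 of 308, 331 of 396, 109 of 132, 32 of 44 and 68 of 88 for lists. The number of arrays limits the small changes that can be called.

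The replicate block gave 602 genes for adhesion with VEGF, 2 for adhesion without VEGF, 621 for the average adhesion effect, 17 for the interaction, 2701 for VEGF in spread and 3140 for VEGF in unspread arrays, each with all genes of the fit without it, and by construction it removes the spread between replicate numbers. Only the 6 arrays compared gave 67 genes for adhesion with VEGF (59 shared) and 451 for VEGF in spread arrays (442 shared), but 1864 for VEGF in unspread arrays (1531 shared), and the cause was not tested. Array weights gave 966 for adhesion with VEGF, 484 for the average adhesion effect, 10 for the interaction, 2170 for VEGF in spread and 3063 for VEGF in unspread arrays, and the cause was not tested. Every probe set on its own gave 385, 350, 5972 (average VEGF effect), 0, 2219 and 3153 in the order adhesion with VEGF, average adhesion, average VEGF, interaction, VEGF in spread and VEGF in unspread, with 30325 features tested. Without the 4 arrays of replicate 2 there were 22 genes (20 shared) for adhesion with VEGF, 2 for average adhesion, 1984 (1844 shared) for average VEGF, 0 for the interaction, 325 (297 shared) for VEGF in spread and 771 (714 shared) for VEGF in unspread arrays, from fewer arrays.

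Arrays shifted to 1 median gave 1 gene for adhesion without VEGF and 4 for the interaction. The interaction gave 2 genes with trend and robust variance, 0 without a filter, 5 with a stricter filter, 3 with the mean of a gene's probe sets and 0 without probe sets ending in _s_at or _x_at, and the cause was not tested. Without these probe sets MYL9 (0.04958) and RRP12 (0.2634) reversed for VEGF in spread arrays, with another probe set for the gene. Camera with an estimated correlation called 0 lists for either adhesion effect and the interaction, 2 for VEGF in spread and 5 for VEGF in unspread arrays. With the block added it called 0, 0, 0, 1 and 1. Fry called 3 lists for adhesion with VEGF, 1 without VEGF and 0 for the interaction, and with the block 0 for adhesion without VEGF and 0 for the interaction. The stricter filter called 1 list for the interaction.

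Leaving out each array in turn gave 95 to 241 genes for adhesion with VEGF, 0 to 2 without VEGF, 117 to 222 for the average adhesion effect, 2634 to 3093 for the average VEGF effect, 0 to 5 for the interaction, 759 to 1359 for VEGF in spread and 1076 to 2013 for VEGF in unspread arrays. Lists numbered 4 to 8, 3 to 7 and 1 to 4 for adhesion with VEGF, adhesion without VEGF and the interaction, and 13 to 17 and 16 to 19 for VEGF in spread and unspread arrays. The mitosis median ranged from -1.38 to 0.0213 for VEGF in unspread arrays and from -0.468 to 0.946 for adhesion without VEGF, and DNA replication from -0.201 to 0.376 there. Without unspread without VEGF replicate 2, mitosis reversed to 0.0213 (adjusted p = 0.944) for VEGF in unspread arrays and to -0.468 for adhesion without VEGF, where DNA replication reversed to -0.201.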

Other observations

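The lists of metallothioneins, guidance genes, proteasome subunits, aminoacyl-tRNA synthetases, lysosome genes and LXR targets, and thus all tests on them, were chosen after the data had been seen. The values of some members had been seen before, among them MT1X, SEMA3G, PLXNA4, EPHA7, EPHB6, UNC5B, EFNB2 and SREBF1. The splits that part every pair, and the use of the lower array and of the SD in the test of fewer cycling cells, were also chosen after the results were seen, unlike the other tests on mitosis genes, normalization and splits.

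Metallothioneins, which bind zinc and copper, fell with the VEGF label averaged over both levels of spreading. All 6 measured were lower, with a median of -2.00 (adjusted p = 7.51e-07, but 0.087 with an estimated correlation). MT1X fell by 2.13 (standard error 0.286, adjusted p = 0.000427), MT1F by 2.08 and MT2A by 2.01 (standard error 0.268, adjusted p = 0.000401). The median was -1.49 in spread and -2.51 in unspread arrays, and the interaction was -0.94 (adjusted p = 0.000418, but 0.49 with an estimated correlation). Proteasome subunits had 4 of 23 lower and a median of -0.19 (adjusted p = 0.0016, but 0.22 with an estimated correlation).

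Semaphorins, plexins, ephrins and their receptors, which guide growing axons and vessels, went mostly up with the VEGF label. Of 26 measured, 14 rose and 4 fell, with a median of 0.44 (adjusted p = 0.0016, but 0.087 with an estimated correlation). The secreted semaphorin SEMA3G rose by 2.17 ± 0.47 (adjusted p = 0.00661), the receptor EPHA7 by 1.88 ± 0.29 (adjusted p = 0.000903), the transmembrane semaphorin SEMA6A by 1.72 ± 0.19 (adjusted p = 0.000139) and the ligand EFNA1 by 1.49 ± 0.22 (adjusted p = 0.000794). The receptor EPHA2 fell by 1.26 (standard error 0.265, adjusted p = 0.00572) and the semaphorin SEMA3A by 0.90. Lysosome genes had 7 of 23 higher, among them the galactosidase GLA at 1.04, with a list median of 0.20 (adjusted p = 0.0121, but 0.22 with an estimated correlation).

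Sterol synthesis genes fell with the VEGF label in spread and unspread arrays. Under the other normalizations 100% of the list's median change was left, which argues against differences left between the deposited arrays as the whole cause. The values were already normalized by GCRMA, so that step and its background correction were not tested. Activation of LXR, a sterol sensor that induces ABCA1 and ABCG1, may take part. Its other targets had a median of 0.233 (adjusted p = 0.0282, but 0.22 with an estimated correlation), with 6 of 15 higher and 2 lower. Their median was 0.189 in spread arrays (adjusted p = 0.0481, but 0.32 with an estimated correlation). In unspread arrays it was 0.161 and did not pass (adjusted p = 0.0644). Whether LXR lowered the synthesis genes was not tested. MYLIP (1.30) and SREBF1 (0.92, also in the sterol list) rose, while SCARB1 fell by 1.23. Lower growth signalling could take part too, since 14 aminoacyl-tRNA synthetases had a median of -0.857 with 10 lower (adjusted p = 9.96e-11, and 0.016 with an estimated correlation). Neither test parts these causes from each other, from a direct effect of VEGF or, if the group names were exchanged, from one of adhesion.

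The mitosis list was lower with the VEGF label mainly in replicate 2. The data are consistent with more cycling cells in replicate 2 of both groups without VEGF, where the lower of the 2 arrays had a list median 1.29 above the highest of the other 4. Fewer cycling cells in the replicate 2 arrays with VEGF than in the others with VEGF is argued against, since the lower of these (6.336) lay 1.11 above the lowest of the other 4, whose SD was 0.599, and the higher (7.049) above all 4. Within replicate 2 the median change was -1.38 in spread and -1.51 in unspread arrays, and whether VEGF acted more strongly there was not tested. What differed in replicate 2 is not given in the labels, and no biological explanation was tested.

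For the average VEGF effect, 1 of 100 splits of the 12 arrays, the real one, gave as many genes as the 3215 called. The highest of the others gave 13. The other splits mix arrays that differ by label, so a real effect would widen their spread within groups and lower their counts. These splits therefore do not exclude chance. Among all 32 splits that part every pair of arrays with the same number, again only the real one gave as many, a share of 3.12%, and the highest of the others gave 323. For the average adhesion effect it was 1 of 100, with 213 genes called and 8 in the highest of the others. Among the splits that part every pair it was 1 of 32, with 62 in the highest of the others. Without the 4 arrays of replicate 2 only 2 genes were called. Chance is not excluded here either, since these splits mix labels too. The comparisons of 3 arrays with 3 have 10 splits each, too few for a share under 0.05. The real split gave 206 genes for adhesion with VEGF against 1 in the highest of the others, 1444 against 0 for VEGF in spread arrays and 1843 against 0 for VEGF in unspread arrays, where 1 split each gave as many as the real one. For adhesion without VEGF the real split gave 0 genes, as did all 10.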
